A study of Mus musculus with 20 samples.

How the data were processed

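RNA from the gastrocnemius, a calf muscle, of mice given an antibody against myostatin (JA16) or saline was measured on Affymetrix mouse genome arrays, with 10 samples in each group. Per the labels' protocols, the antibody was injected into the peritoneum on day 1 (0.12 mg per g body weight) and day 3 (0.09 mg per g), and the mice were killed on day 5. The muscle was frozen in liquid nitrogen, RNA was extracted with Trizol, and cDNA was amplified and labelled with a NuGEN kit, per the same protocols. The labels do not say of each sample that it came from its own mouse. If several came from 1 mouse, the p-values measure only the spread between these samples, part of which is then technical.

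The deposited values are array intensities on a linear scale, 1 per probe set and sample, which the submitters' processing notes attribute to MAS5, with no version. Masking, scaling target and detection calls are not given in the sources used here. Each of the 20 arrays had the same mean intensity once the lowest and highest 2% of probe sets were left out, which shows that the arrays had been scaled to one trimmed mean. Median intensities ran from 38.9 to 77.1 between arrays. No scanner files were used here, so background subtraction and summarisation are those of the deposited table. The number of arrays limits the precision. Scaling to one trimmed mean removes a factor common to an array, while differences in the shape of the distribution, seen in the medians, stay.

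The table held 45101 probe sets, of which 64 were controls. The platform annotation listed 1 gene for 34945 probe sets, several for 932 and none for 9160. Probe sets with several genes or none were not named. Symbols were checked by gene identifier against a RefSeq gene table of assembly GRCm38.p6. Identifiers matched for 34754 of the single-gene probe sets and did not match for 204, controls included, and no symbol needed an update. No coordinates were used, since no genome build is named for the array table. Mstn, which encodes myostatin, and Amd1 had no single-gene probe set in the annotation used and are not analysed here.

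Intensities at or below 0 (5 values) were set to the smallest positive value, 0.1, and log2 was taken. Probe sets entered if their mean log2 intensity over all 20 samples was at or above the median of all probe sets (5.65, an intensity of 50.1). Each gene was represented by its probe set with the highest mean, which left 11200 genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), JA16 minus saline, with a two-sided moderated test and Benjamini-Hochberg adjustment over the 11200 genes and a threshold of 0.05. Fold changes are on the log2 scale of MAS5 intensities. Data were joined with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9.

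The labels give both groups the replicate numbers 1 to 10, and the array numbers in the labels are adjacent within each number. The saline sample has the lower array number in every pair, so array order within pairs cannot be told apart from treatment. Whether the numbers pair the samples was checked from the data. The deviations of same-numbered samples from their group means correlated across genes at 0.377 to 0.786 in all 10 pairs, against a median of -0.11 between differently numbered samples. A saline sample correlated best with the JA16 sample of its own number in 6 of 10 cases, and a JA16 sample with its own saline partner in 5 of 10. All 10 pair correlations were above the limit of 0.1 set for pairing, and the numbers were taken to pair the samples. The fit without the block, fixed before the data were examined, remained the main comparison. The fit with the replicate number as a block, also fixed then, is given beside a result where it changed the call. No sample was a copy of another: correlations between arrays over all probe sets ran from 0.879 to 0.936.

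Gene lists were also fixed before the data were examined. They covered collagens, other extracellular matrix, TGF-beta and activin signalling, myogenic regulators, the cell cycle, atrophy and autophagy, IGF and mTOR signalling, ribosomal proteins, ribosome biogenesis, translation factors, aminoacyl-tRNA synthetases, polyamine synthesis, slow fibre genes, fast fibre genes, embryonic muscle genes, oxidative phosphorylation, fatty acid oxidation, glycolysis, the proteasome, chaperones, immediate early genes, the circadian clock and the interferon response. Marker lists covered macrophages and leukocytes, adipocytes, endothelial and mural cells, fibroblasts and tendon, nerve and Schwann cells, and blood cells, and sex-linked genes served only as a sample check. The 28 lists with at least 5 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists. The test was repeated with an estimated correlation and with fry, which asks whether members move on balance one way. Blood cell markers had 4 measured members and were not tested.

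The genes named were set by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls past the threshold, or all where fewer passed, and the 5 smallest p in a direction where fewer than 5 passed. Acvr2b, Fst, Smad7, Col1a1, Col3a1, Fbxo32, Trim63, Smox, Igf1, Myh2 and Myh7 were always included. The rule added the 4 smallest p of each list past the threshold and 2 of each other list. Genes that passed only with the replicate block, and any other gene named, were chosen after their values were seen.

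Alternatives fixed in advance were the block, no filter, the brightest probe sets only (above the 75th percentile), quantile normalization, centring of array medians, a pseudocount of 9.1 (the 20th percentile of intensities), the mean over probe sets, probe sets without cross-matching endings, a test per probe set, other variance models, array weights, array number, RNA quality and slow fibre content as covariates, and leaving out each sample. RNA quality was the mean log2 ratio of 3' to 5' signal of the Gapdh and beta-actin control probe sets. Chosen after seeing the data were a split of replicates 1 to 6 from 7 to 10, the block together with each other choice, leaving out whole pairs, exact sign flips of the 10 pair differences of each list, and counts of genes after swaps of samples within pairs.

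The procedure was tested on simulated data for the comparison of JA16 with saline over 11200 genes, with 200 genes changed by known folds and the pair means and within-pair spread of the real samples. Without the block, 54.5% of genes changed 2-fold, 13.4% of those changed 1.5-fold and 0 of those changed 1.25-fold were recovered, with 0 false calls. With the block, the shares were 89.4%, 55.2% and 38.8%, with 4 false calls. The simulated noise was drawn for each gene on its own, without the correlation between genes of the real data. The false calls therefore say little about the real fits. The real pair means already hold part of the within-pair noise, which widens the simulated spread and lowers recovery without the block.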

Results

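Gene expression was measured in gastrocnemius muscle of mice treated with JA16, an antibody that binds myostatin, a secreted inhibitor of muscle growth, or with saline. The comparison of 10 JA16 samples with 10 saline samples asks how muscle transcripts differ 4 days after the first injection. The values are MAS5 intensities from 20 arrays, all scaled to one trimmed mean, with array medians between 38.9 and 77.1. Means are given ± SD with n = 10 per group. Fold changes are log2 of JA16 over saline, with their standard errors (SE) from limma.

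Mss51, a gene expressed mainly in skeletal muscle and tied to mitochondrial metabolism, fell most. Its intensity was 7686 ± 1554 in saline and 2743 ± 1421 in JA16 samples, a log2 fold change of -1.63 (SE 0.23, limma adjusted p = 0.00247), and it was lower in JA16 in all 10 pairs. Junos, a transcript from the strand opposite Jun, fell by 1.43 (SE 0.20, limma adjusted p = 0.00247), from 410 ± 134 to 149 ± 38.9. Ddah1, an enzyme that degrades methylarginine inhibitors of nitric oxide synthase, fell by 1.12 (SE 0.19, limma adjusted p = 0.0278), and both of its probe sets had the same direction. The Riken transcript A930003A15Rik rose by 1.14 (SE 0.20, limma adjusted p = 0.0306), from 446 ± 125 to 1004 ± 378, and was higher in JA16 in all 10 pairs. These 4 of 11200 genes passed an adjusted p of 0.05 in limma without the block, 1 higher and 3 lower, and 297 genes had an unadjusted p under 0.05 where chance gives 560. Mss51 and Junos passed with any 1 sample left out. The call of A930003A15Rik was lost without any 1 of 13 samples (saline replicates 1, 3, 4, 5, 8 and 10, JA16 replicates 1, 3 and 6 to 10), with adjusted p between 0.0541 and 0.0883. That of Ddah1 was lost without any 1 of 10 (saline replicates 3, 5, 6 and 8, JA16 replicates 1, 3, 6, 7, 9 and 10), with adjusted p between 0.0541 and 0.0853. The fit without the block keeps the shared deviations of same-numbered samples in its spread. With the replicate block 1820 genes had an unadjusted p under 0.05. With it 31 genes passed the adjusted threshold, 17 higher and 14 lower, and all 4 were among them. With the block and 1 pair left out the number of genes passing was between 10 and 51. It moved by over 1.5 times without pair 1 (51 genes), 4 (10), 6 (11), 7 (14), 8 (16) or 9 (16).

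**Figure D1:**
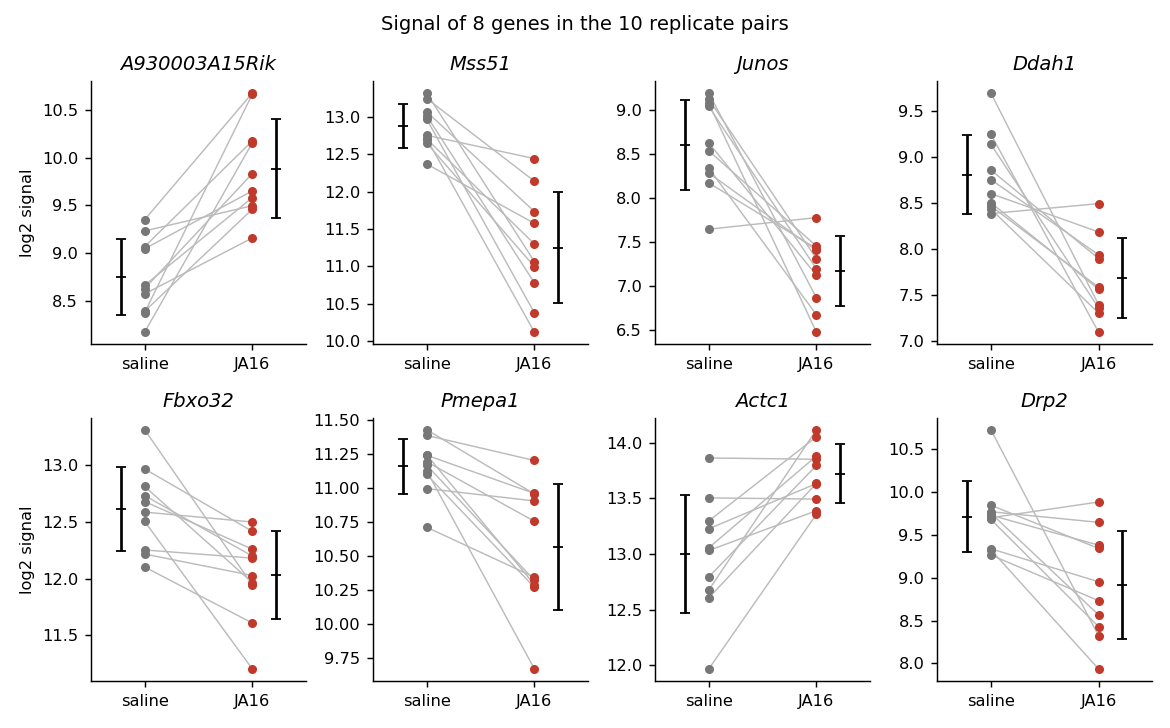
Log2 MAS5 intensity (vertical axes) of 8 genes in saline (grey) and JA16 (red) samples, with a line joining the samples of each of the 10 replicate numbers and bars for the group mean ± SD. Mss51 was lower in JA16 in all 10 pairs and A930003A15Rik higher in all 10. Fbxo32 and Drp2 did not pass over all genes in either fit, and Pmepa1 and Actc1 passed only with the block.

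Of the genes called with the block, 27 were not called without it and were chosen after their values were seen, except Actc1, Cnbd2, Rps6ka5, Dglucy and Pmepa1, which the rule also named. Actc1, the cardiac form of alpha-actin, rose by 0.72 (SE 0.13, blocked limma adjusted p = 0.0339), from 8692 ± 3077 to 13705 ± 2508. Cnbd2 rose by 1.08 (SE 0.14, adjusted p = 0.00481). Other rises were Stbd1, which binds glycogen, at 0.76, Calml4 at 0.78, the carbonic anhydrase Car14 at 0.67, Popdc2 at 0.52, the melusin gene Itgb1bp2 at 0.37 and Cct5, a subunit of the chaperonin that folds actin, at 0.26. Pla2g4e, Prr15, Aimp2, Rnf144b, Hacd1, Mlec, Tnfaip2 and Sypl2 completed the 17, with log2 fold changes between 0.32 and 0.52. The falls included Otub2, a deubiquitinase, at -0.93 (SE 0.11, adjusted p = 0.0033), Prima1, which anchors acetylcholinesterase in membranes, at -0.94, Art5 at -0.86 and Dglucy at -0.77. They also included the kinase gene Rps6ka5 at -0.72, Tbc1d1, a regulator of glucose uptake, at -0.57, Pmepa1, a TGF-beta target that damps the pathway, at -0.59, Bicc1 at -0.59, Gcnt2 at -0.43, the integrin gene Itgb5 at -0.35 and Pnrc1 at -0.29. For Rnf144b, 2 of 3 probe sets had this direction.

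The arrays split into 2 sets by the ratio of 3' to 5' signal of the beta-actin control probe sets. Its log2 value was 1.33 to 1.84 in replicates 1 to 6 and 0.48 to 0.64 in replicates 7 to 10, in both groups. The Gapdh ratio overlapped between these sets (0.21 to 0.41 and 0.18 to 0.32), so the split rests on beta-actin alone. Within pairs the beta-actin ratio was lower in JA16 by 0.13 on average, in 8 of 10 pairs (exact two-sided sign-flip p = 0.0645). All 31 genes had the same sign in both array sets, although they were selected on all samples. In fits of each set with the block, Mss51 was at -1.78 (SE 0.23) in replicates 1 to 6 and -1.40 (SE 0.25) in replicates 7 to 10, and A930003A15Rik at 1.07 (SE 0.19) and 1.23 (SE 0.25). Over all pairs the blocked SE was 0.20 for Mss51 and 0.17 for A930003A15Rik. Neither array set alone gave a gene past the threshold in limma, with 0 genes each, and 1099 and 799 genes had an unadjusted p under 0.05 with the block. With the array set as the block, 9 genes passed, all among the 31. Adding the control ratio as a covariate to the replicate block left 2 genes, Otub2 and Tbc1d1, and centring array medians left 10 of the 31. The median share of the 31 fold changes kept was 0.929 and 1.06, and with the SE of the blocked fit 25 and 31 of them would have passed.

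**Figure D2:**
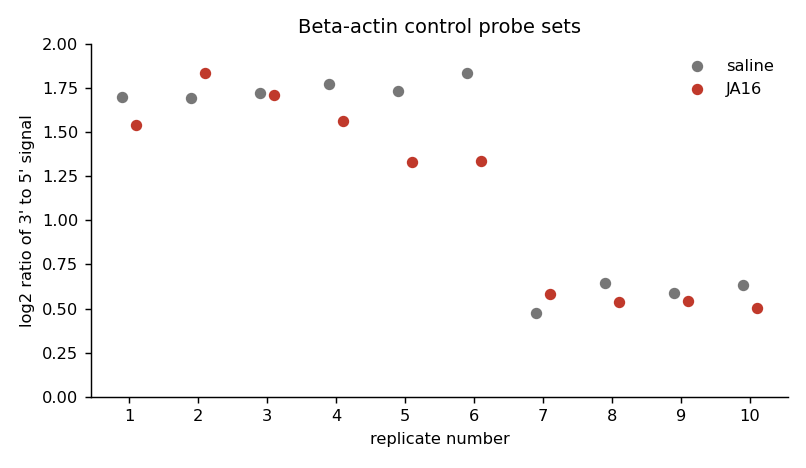
Log2 ratio of 3' to 5' signal of the beta-actin control probe sets (vertical axis) by replicate number (horizontal axis) in saline (grey) and JA16 (red) samples. Replicates 1 to 6 lie between 1.33 and 1.84 and replicates 7 to 10 between 0.48 and 0.64.

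Of the genes fixed in advance, none passed over all genes in the fit without the block or in that with it. Fbxo32, the ubiquitin ligase atrogin-1, was at 6468 ± 1727 in saline and 4309 ± 1032 in JA16 samples (log2 fold change -0.59, SE 0.16, limma adjusted p = 0.829). It was lower in all 10 pairs (blocked adjusted p = 0.0579) and passed with quantile normalization and the block together, while Trim63, the other main atrophy ligase, was at -0.10 (SE 0.12). Smox, the spermine oxidase, was at 0.52 (SE 0.16), Igf1 at 0.35 (SE 0.28), with 3 of 4 probe sets in this direction, and the activin receptor gene Acvr2b at -0.013 (SE 0.25). Acvr2b was at 0.062 with quantile normalization. Fst, the myostatin-binding follistatin, was at -0.58 (SE 0.21) and Smad7 at -0.30 (SE 0.14). Col1a1 was at -0.15 (SE 0.15) and Col3a1 at 0.10 (SE 0.18), with its 2 probe sets in opposite directions. The myosin genes Myh2 and Myh7 were at -0.29 (SE 0.29) and -0.77 (SE 0.50). With 1 sample left out Myh2 ran from -0.39 to 0.013 and Myh7 from -1.02 to -0.39. JA16 replicate 3 was the lowest JA16 sample for both. The smallest p that missed the threshold without the block were those of Cnbd2, Tph1 at 1.15, Actc1 and Ripor2 at 0.61 among higher values, and those of Rps6ka5 and Dglucy among lower ones. Col3a1 was at -0.084 and Igf1 at -0.16 when probe sets with cross-matching endings were left out.

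Camera with the preset correlation called 11 of 28 lists, and 12 with the replicate block, but with an estimated correlation it called 0, with or without the block, and fry called 0 without the block and 1, ribosomal proteins, with it. Of the 11, all but polyamine synthesis (-0.029) had an estimated correlation above the preset 0.01. It was 0.73 for slow fibre genes, 0.68 for fast fibre genes, 0.54 for nerve markers and 0.31 for ribosomal proteins. A preset below the true correlation makes the p-values too small. The median over all genes was -0.016, so that list values are close to changes relative to it, and 0.054 with centred medians. Of the 11 lists, the 5 higher ones lay above the mean of all genes in 8 of 10 pairs each. The 6 lower ones lay below it in 9 pairs for nerve markers (exact sign-flip p = 0.00977), 7 each for fibroblast markers (0.131), immediate early genes (0.238) and other matrix (0.262), 6 for TGF-beta (0.0547) and 5 for slow fibre genes (0.414). Adjusted over the 28 lists, 0 passed by sign flips (lowest adjusted p = 0.137).

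Genes of TGF-beta and activin signalling, the pathway of myostatin, were for the most part lower. Of 25 measured members 21 were lower in JA16, with a median of -0.12 (camera adjusted p = 0.000322, adjusted p = 0.173 with an estimated correlation). Over all genes 0 members passed without the block and 1, Pmepa1, with it. Adjusted over the list alone, 1 passed without the block and 6 with it, all lower: Pmepa1, Skil at -0.40, Smad7, Fst, Ccn2 at -0.48 and Tgif1 at -0.43. The list mean was -0.078 in replicates 1 to 6 and -0.31 in replicates 7 to 10. With the block, Fst was at -0.15 (SE 0.20) and -1.23 (SE 0.19) in these sets, against an SE of 0.20 over all pairs in the blocked fit. Other matrix and collagen processing genes were lower for 30 of 34 members (median -0.11, camera adjusted p = 0.0209, adjusted p = 0.642 with an estimated correlation), with means of -0.089 and -0.34 in the array sets. The lysyl oxidase gene Lox was at -0.83 (SE 0.43) and Fmod at -0.41 (SE 0.31), and 0 members passed. Fibroblast and tendon markers, which share Dcn, Fmod and Thbs4 with the matrix list, were lower beside both lists (median -0.22, means of -0.20 and -0.65 in the array sets). The matrix call was lost without any 1 of 7 samples (saline replicates 2, 7 and 10, JA16 replicates 3, 4, 5 and 10; adjusted p between 0.0661 and 0.593). The last value is that without saline replicate 7, which held the highest saline intensities of Lox and Fn1 and without which the median was -0.036, and it was 0.00203 when JA16 replicate 3 was left out as well. The collagen list was not called (median 0.063, mean -0.0501, test direction up, adjusted p = 0.724).

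Genes of protein synthesis differed little in size. All 35 measured ribosomal protein genes were higher in JA16, with a median of 0.086 (camera adjusted p = 6.44e-07, adjusted p = 0.369 with an estimated correlation), and 0 passed singly. Rpl12 was at 0.52 (SE 0.19), Rpsa at 0.14 (SE 0.0902) and Rpl7 at 0.10 (SE 0.058). The Rpl12 probe set was dim, with a mean intensity of 168 in saline, against 13833 for Rpsa and 11541 for Rpl7. The list means were 0.10 and 0.11 in the array sets, and with quantile normalization the median was 0.023 and the call was lost (adjusted p = 0.115). Polyamine synthesis was called without the block (median 0.071 over 8 members, adjusted p = 0.0314, adjusted p = 0.173 with an estimated correlation) and not with it (adjusted p = 0.0757). Its means were 0.027 and 0.20 in the array sets. Adjusted over the list alone, 2 members passed in both fits, Smox and the ornithine decarboxylase gene Odc1 at 0.35 (SE 0.10). The polyamine call was also lost with quantile normalization (median 0.0015, adjusted p = 0.137), with centred medians (adjusted p = 0.115) and without any 1 of 7 samples (saline replicates 8, 9 and 10, JA16 replicates 3, 4, 5 and 7; adjusted p between 0.0607 and 0.119). Translation factors (median 0.057, adjusted p = 0.294), aminoacyl-tRNA synthetases and amino acid supply (0.049, adjusted p = 0.263), ribosome biogenesis (-0.00091, test direction up, adjusted p = 0.724) and chaperones (0.021, adjusted p = 0.568) were not called. With quantile normalization the chaperone median was -0.0087. The proteasome list had a median of 0.046 and was not called without the block but called with it (adjusted p = 0.0573 and 0.0263, adjusted p = 0.835 with the block and an estimated correlation). With quantile normalization and the block its adjusted p was 0.992. Without the block it was called with centred medians (median 0.12, adjusted p = 0.0334) and without any 1 of 5 samples (saline replicates 1, 8 and 9, JA16 replicates 1 and 5; adjusted p between 0.00445 and 0.0453).

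Fibre type and energy metabolism lists moved in several directions. Slow and oxidative fibre genes were lower for 15 of 17 members, with a median of -0.41 (camera adjusted p = 0.00108, adjusted p = 0.642 with an estimated correlation). Tnnt1 was at -0.83 (SE 0.55), Myh7b, with low mean intensities of 100 in saline and 60.0 in JA16, at -0.89 (SE 0.53) and Atp2a2 at -0.51 (SE 0.30), and 0 members passed. This rested on JA16 replicate 3, without which the median was -0.053 (adjusted p = 0.798), and the list means were -0.62 in replicates 1 to 6 and -0.042 in replicates 7 to 10. Fast glycolytic fibre genes were higher for 20 of 21 members (median 0.064, adjusted p = 0.000445, adjusted p = 0.642 with an estimated correlation) and oxidative phosphorylation genes for 45 of 51 (median 0.065, adjusted p = 8.24e-05, adjusted p = 0.642 with an estimated correlation). Under quantile normalization both medians turned, to -0.0021 and -0.0025, and both calls were lost (adjusted p = 0.979 and 0.959). Their means in the array sets were 0.042 and 0.12 for fast fibre genes and 0.033 and 0.11 for oxidative phosphorylation, and without saline replicate 7 the latter was not called (adjusted p = 0.0783). Glycolysis and glycogen genes were higher for 20 of 25 members (median 0.063, adjusted p = 0.0147, adjusted p = 0.642 with an estimated correlation), with means of 0.018 and 0.0796, and were not called without any 1 of 4 samples (saline replicates 7 and 10, JA16 replicates 2 and 3; adjusted p between 0.0667 and 0.132). With quantile normalization the glycolysis list was not called either (median 0.015, adjusted p = 0.979). It shares Pfkm, Aldoa, Pgam2, Eno3, Ldha and Pygm with the fast fibre list, so the calls of these lists are not independent. Adjusted over the list alone and with the block, Gpd1 at 0.27 passed in the fast fibre list and the monocarboxylate transporter gene Slc16a3 at 0.36 in the glycolysis list. Over all genes 0 members of these lists passed in either fit.

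Growth and differentiation lists were not called. Atrophy, autophagy and FoxO genes had a median of -0.027 (adjusted p = 0.294) and were called with quantile normalization (-0.0802, adjusted p = 0.0214), and adjusted over the list alone Fbxo32 passed in both fits and Gadd45a, at 0.45, with the block. Myogenic regulators had a median of -0.0504 (adjusted p = 0.568), IGF and mTOR signalling -0.033 (adjusted p = 0.724), the cell cycle -0.061 (adjusted p = 0.724), with Mcm2 at 0.42 passing adjusted over the list alone with the block, and fatty acid oxidation -0.0299 (adjusted p = 0.724). Without saline replicate 7 the cell cycle median was 0.047, with the test direction up. The cell cycle means were 0.065 in replicates 1 to 6 and -0.25 in replicates 7 to 10. Embryonic muscle genes had a median of -0.10 with the test direction up (adjusted p = 0.724). Of these, Actc1 passed adjusted over the list alone in both fits, and Gadd45a and Ncam1, at -0.63, with the block. Saline replicate 7 held the highest values of this list, and without it the median was 0.19 (adjusted p = 0.0455).

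All 6 measured markers of nerve and Schwann cells, of 15 in the list, were lower in JA16, with a median of -0.60. Camera called the list with the preset correlation of 0.01 (adjusted p = 3.27e-06) but not with the estimated one of 0.54 (adjusted p = 0.173). Drp2 was at -0.79 (SE 0.23), S100b at -0.82 (SE 0.35), the myelin basic protein gene Mbp at -0.59 (SE 0.26), with 6 of 7 probe sets lower, and Pmp22 at -0.28 (SE 0.12). Ncmap was at -0.61 (blocked SE 0.154) and Sox10 at -0.21 (blocked SE 0.145). Over all genes 0 passed, and adjusted over the list alone 1 passed without the block and 5 with it. The list means were -0.57 and -0.52 in the array sets. Fibroblast and tendon markers were lower for 14 of 17 members (median -0.22, adjusted p = 0.000322, adjusted p = 0.369 with an estimated correlation), with means of -0.20 and -0.65. The tendon genes Tnmd at -0.99 (SE 0.48), Kera at -0.88 (SE 0.46), Comp at -0.84 (SE 0.45) and Mkx at -0.88 (SE 0.28) led it, and of these Mkx passed adjusted over the list alone with the block. Mkx was dim, with mean intensities of 95.4 in saline and 47.8 in JA16, near the intensity filter of 50.1. Immediate early genes were lower for 18 of 23 members (median -0.19, adjusted p = 0.000473, adjusted p = 0.369 with an estimated correlation), with means of -0.092 and -0.34. Adjusted over the list alone, Egr2 at -0.49 passed in both fits and Klf6 and Ccn1 with the block. Endothelial and mural markers had a median of -0.11 and were not called without the block but called with it (adjusted p = 0.0996 and 0.0436, adjusted p = 0.804 with the block and an estimated correlation). With the block their adjusted p was 0.0691 with quantile normalization and 0.129 with centred medians. Without the block they were called without any 1 of 6 samples (saline replicates 3 to 6, JA16 replicates 8 and 9; adjusted p between 0.00217 and 0.0496). Macrophage and leukocyte markers (median -0.10, adjusted p = 0.488), adipocyte markers (-0.20, adjusted p = 0.663), the interferon response (-0.073, adjusted p = 0.724) and the circadian clock (-0.0404, adjusted p = 0.724) were not called. Without JA16 replicate 1 the macrophage median was -0.24 and the adipocyte median -0.39, and both were called (adjusted p = 0.00392). The macrophage median was 0.044 without saline replicate 7, and its list means were 0.13 in replicates 1 to 6 and -0.44 in replicates 7 to 10. Usp18 of the interferon list, at 0.45, passed adjusted over the list alone with the block. Of 4 blood cell markers, Bpgm was at 0.14, S100a9 at 0.012, Alas2 at -0.10 and S100a8 at -0.40, and 0 passed.

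**Figure D3:**
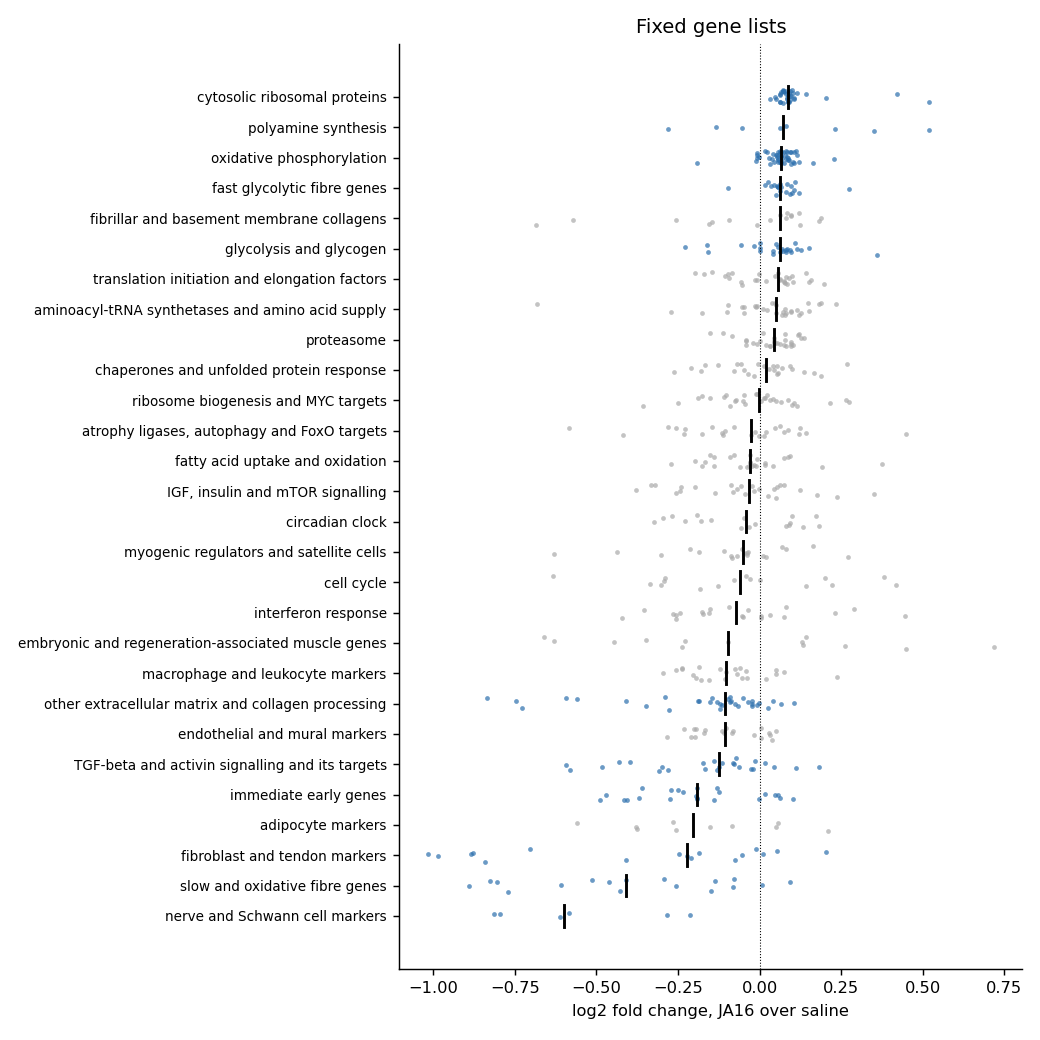
Log2 fold change of JA16 over saline (horizontal axis) for the measured members of the 28 tested lists (vertical axis), with black bars for list medians and blue points for the 11 lists called by camera with the preset correlation, none of which was called with an estimated correlation. Medians ran from -0.60 for nerve and Schwann cell markers to 0.086 for ribosomal proteins, and those of fast fibre genes and oxidative phosphorylation changed sign with quantile normalization.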

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

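Of the tests below, all but 1 were chosen or bounded after the results they measure had been seen; the exception is the fit of TGF-beta targets with fibroblast and tendon markers as a covariate.

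Samples that stood apart from the other 9 of their group were sought for the named genes, the 28 list means and the beta-actin ratio, by the gap to the nearest sample over the range of the group. Of 284 tests 29 passed, where chance gives about 1 in 20, or 14.2. Saline replicate 7 accounted for 13, each time as the highest of its group: Col12a1 (0.565), Lox (0.669), Fn1 (0.576), Ncam1 (0.602), Mki67 (0.734), Cd163 (0.555) and C1qa (0.514) among genes, and other extracellular matrix (0.563), myogenic regulators (0.664), the cell cycle (0.606), embryonic muscle genes (0.771), the interferon response (0.676) and macrophages (0.495) among list means. JA16 replicate 3, whose array label carries an extra suffix, accounted for 6, each time as the lowest: Myh2 (0.802), Myh7 (0.4661), Myh7b (0.483), Tnnt1 (0.616), slow fibre genes (0.649) and fatty acid genes (0.486). Its slow fibre mean was 9.21 on the log2 scale, against 11.95 to 13.43 in the other JA16 samples.

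JA16 replicate 1 was highest for the cell cycle list (0.51) and adipocyte markers (0.553), and lowest for Ndufa4 (0.593) and Prima1 (0.493). JA16 replicate 5 was lowest for Smox (0.484), JA16 replicate 10 for Eif5a (0.514), JA16 replicate 8 for Canx (0.53) and JA16 replicate 7 for Pnrc1 (0.605). JA16 replicate 2 was highest for Ndufv2 (0.485) and saline replicate 3 for Drp2 (0.603).

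In 100 splits of the 20 samples, the real one included, 4 gave as many genes as the real split (4), with 2527 genes as the highest of the others, but most of these splits keep some pairs together. The 3 larger splits called 1775, 1967 and 2527 genes, which points to a structure of the samples: they put 9, 8 or 4 of the 12 arrays of replicates 1 to 6 in one group, where the real split has 6, and parted 4, 4 or 2 of the pairs, where the real one parts 10. The array set alone does not give such counts, since other splits with 9, 8 or 4 of those arrays in one group gave 0 genes, and which structure does was not tested. With the array set as a block 9 genes passed. Of these splits 2 others part all 10 pairs, which is too few for a share under 0.05, and gave 0 genes. Swaps within pairs part all 10 pairs. In 100 of them only the real one, 1 of 100, gave 4 genes without the block, and likewise 31 with it. The highest of the others gave 0 in both fits. This argues against chance for both counts, but 100 swaps bound its share only to about 1 in 100. For lists, 13 of 100 splits gave at least the real 11, with 13 as the highest other, and 23 of 100 swaps gave at least 12 with the block, with 18 as the highest other, so chance is not excluded for the number of lists called.

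The 31 genes called with the block were weighed against RNA quality and array scaling. With the 3' to 5' ratio as a covariate beside the block, the median share of the fold change kept was 0.929 (quartiles 0.867 and 0.994), the median size going from 0.59 (SE 0.098) to 0.58 (SE 0.115), and 2 genes stayed past the threshold. With its fold changes and the SE of the blocked fit 25 would have passed, and with the fold changes of the blocked fit and its SE 3, so the larger SE ended most of these calls. With quantile normalization the share was 0.963 (quartiles 0.929 and 1.03) and 27 stayed past the threshold, and with centred medians it was 1.06 (quartiles 0.915 and 1.16; SE 0.114) and 10 stayed, where the fold changes with the SE before centring would have left all 31. With the covariate and with quantile normalization, the sizes argue against RNA quality or array scaling as the whole cause of the fold changes. Centring adds the same amount to every log2 fold change (the median of all genes went from -0.016 to 0.054). That is small beside the smallest of the 31 (Cct5, 0.26), so the share kept with centring could not test scaling. The number of calls depends on the covariate and on the scaling. An effect of the antibody may account for these genes, a hypothesis found and tested on the same samples. With saline as the only control, binding of myostatin cannot be told apart from an effect of injected antibody as such. Array order within pairs cannot be told apart from treatment either.

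The lower nerve and Schwann cell markers were weighed against a lower share of all cells other than fibres. They lay below endothelial and mural markers by a mean of -0.45, in 8 of 10 pairs (exact two-sided sign-flip p = 0.0195), which argues against an equal loss of both. With the RNA quality covariate the median share kept was 0.888, the median size going from 0.60 (SE 0.161) to 0.60 (SE 0.201), with 0 genes past the threshold over all genes before or after. A lower share of cells other than fibres stays open. A different amount of nerve in the dissected muscle also stays open, as does a change within Schwann cells. The 6 markers fell by unlike amounts, from -0.82 (blocked SE 0.33) for S100b to -0.21 (blocked SE 0.145) for Sox10. Whether a single change in the amount of nerve fits all 6 was not tested.

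The 6 TGF-beta and activin targets that were lower with the block (adjusted over the list alone, and so picked for being lower) were weighed against fewer fibroblasts or tendon cells. With the mean of those markers as a covariate the median share kept was 0.607 (quartiles 0.514 and 0.798), the size going from 0.46 (SE 0.131) to 0.32 (SE 0.116). Pmepa1 was then at -0.41 (SE 0.093), Skil at -0.33 (SE 0.0896) and Tgif1 at -0.41 (SE 0.17), while Ccn2 at -0.24 (SE 0.139), Smad7 at -0.15 (SE 0.0878) and Fst at -0.30 (SE 0.178) lay within 2 SE of 0, so that tissue share and a change within cells cannot be told apart for the 6 as a set. With the RNA quality covariate the share was 1.18 (SE 0.131 before, 0.162 after), and without pair 7 it was 0.84 (size 0.35), so neither accounts for most of it. Inhibition of myostatin signalling stays open as a hypothesis, which saline as the only control cannot tell apart from an effect of injected antibody as such.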

How the results depend on the processing

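The array set, pairs left out, exact sign flips and every combination with the block were chosen after seeing the data. Array signal over background could not be judged, since no detection calls were used, so that genes under the intensity filter stay unknown except in the fit without a filter. Without the block, the named genes had 1611 values under other settings, of which 10, in 6 genes, changed sign, 0 of them past the threshold. The lists had 528 medians, of which 38, in 17 lists, changed sign, 0 of them past the threshold. Of these 22 kept the direction of the test, among them all 7 with centred medians, where the median of all genes went from -0.016 to 0.054 and no list changed side of it. The 31 genes called with the block kept their direction in all 457 values under other settings, and 187 of these were not past the threshold. The block changed no list call other than polyamine synthesis, lost, and the proteasome and endothelial markers, gained. The cause of a change was not tested, except where fewer samples or genes were tested and for the calls lost with the block when the RNA quality covariate or centred medians were added, which a larger SE ended for the most part.

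The 4 genes (1 higher, 3 lower) and 11 lists of the fit without the block became 31 genes (17 higher, 14 lower) with it. The brightest probe sets gave 2 genes, 1 of them lower, and an embryonic median of 0.13. Quantile normalization gave 7 lists, with medians of 0.021 for ribosome biogenesis, -0.0021 for fast fibre genes, -0.0025 for oxidative phosphorylation and -0.0087 for chaperones, and Acvr2b at 0.062 and Oaz2 at -0.0062. Centred medians, which move all genes alike, gave 2 genes, 0 higher, with medians of 0.019 for myogenic regulators, 0.0082 for the cell cycle, 0.043 for atrophy, 0.036 for IGF and mTOR, 0.068 for ribosome biogenesis, 0.039 for fatty acids and 0.029 for the clock, and Acvr2b at 0.056. The mean over probe sets gave a collagen median of -0.0083. Without cross-matching endings the medians were 0.0021 for ribosome biogenesis, -0.0027 for translation factors and 0.017 for embryonic genes, with Col3a1 at -0.084 and Igf1 at -0.16. Probe sets tested singly gave 2, 0 of them higher. Array weights gave 5 lower genes, medians of -0.016 for collagens, -0.01997 for aminoacyl-tRNA synthetases and 0.0083 for the clock, and Acvr2b at 0.015.

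The array number as a covariate gave 9 genes (3 higher, 6 lower). The RNA quality covariate gave 12 (5 higher, 7 lower) and a translation factor median of -0.0023. The slow fibre covariate gave 2, 0 higher, with medians of 0.0086 for embryonic and 0.045 for fatty acid genes and Myh2 at 0.027. The array set as a block gave 9 (4 higher, 5 lower). An estimated correlation and fry each gave 0 lists. Without JA16 replicate 3 and saline replicate 7, 0 genes were higher and 5 lists were called. The medians were then 0.00203 for other extracellular matrix, 0.015 for myogenic regulators, 0.052 for the cell cycle, 0.00101 for ribosome biogenesis, -0.00022 for translation factors, 0.25 for embryonic genes, 0.0295 for interferon and 0.045 for macrophages, with C1qa at 0.039. Replicates 1 to 6 alone gave 0 genes, 0 higher and 0 lower, and 4 lists, with medians of 0.036 for myogenic regulators, 0.00802 for ribosome biogenesis, 0.085 for embryonic genes, 0.00077 for interferon and 0.13 for macrophages. Replicates 7 to 10 alone gave 0 genes, 0 higher and 0 lower, and 13 lists, with medians of -0.15 for collagens, 0.0048 for ribosome biogenesis and 0.016 for fatty acids, Acvr2b at 0.29 and Myh2 at 0.11.

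With the block, the brightest probe sets gave 28 higher genes and 7 lists, quantile normalization 7 lists, and probe sets tested singly 28 higher. Centred medians gave 10 genes (3 higher, 7 lower) and no variance trend 9 (4 higher, 5 lower). The RNA quality covariate gave 2 (0 higher, 2 lower) and the slow fibre covariate 17 (8 higher, 9 lower) and 7 lists. Without pairs 3 and 7 there were 12 genes (5 higher, 7 lower) and 3 lists. Replicates 1 to 6 alone gave 0 genes and 5 lists, and replicates 7 to 10 alone 0 genes and 14 lists, with 0 genes higher and 0 lower in each. An estimated correlation gave 0 lists, fry 1 and exact sign flips 0.

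Leaving out 1 sample at a time gave 2 to 5 genes, 0 to 1 higher, 2 to 4 lower, and 7 to 14 lists. The medians ran from -0.076 to 0.13 for collagens, -0.15 to 0.047 for the cell cycle, -0.072 to 0.015 for atrophy, -0.084 to 0.00054 for IGF and mTOR, -0.043 to 0.042 for ribosome biogenesis, -0.22 to 0.19 for embryonic genes, -0.0901 to 0.027 for fatty acids, -0.065 to 0.0299 for the clock, -0.14 to 0.016 for interferon and -0.24 to 0.044 for macrophages. Acvr2b ran from -0.10 to 0.083 and Myh2 from -0.39 to 0.013. Of the 23 list medians that changed sign, 14 kept the direction of the test, and 1 was past the threshold, the embryonic list without saline replicate 7, with the test direction up in both fits. Leaving out 1 pair at a time with the block gave 10 to 51 genes, 4 to 31 higher, 6 to 20 lower, and 4 to 13 lists.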

Other observations

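Genes just beyond the threshold with the replicate block, all chosen after their values were seen, were mostly higher in JA16. Between adjusted p of 0.05 and 0.1 stood 38 genes, 26 higher and 12 lower. Among the higher were the muscle kinase gene Srpk3 at 0.28 (SE 0.056) and the Z-disc gene Pdlim3 at 0.33 (SE 0.066), each higher in 10 of 10 pairs, Tceal7 at 0.61 (SE 0.122, 10 of 10) and Gamt, an enzyme of creatine synthesis, at 0.75 (SE 0.153, 9 of 10). Among the lower were Arrdc3 at -0.58 (SE 0.133, lower in 10 of 10), Adm at -0.65 (SE 0.138, 9 of 10) and Gna13 at -0.36 (SE 0.078, 10 of 10). None of them passed.

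When each probe set was tested on its own with the block, 45 passed. Of these 34 belonged to genes among the 31, several of them to Itgb5, Aimp2, Hacd1 and Ddah1. Pmepa1, Gcnt2 and Prima1, of the 31, had no probe set past the threshold in this test. A further 8 belonged to other genes whose brightest probe set did not pass: Pgk1 at 0.33, Srpk3 at 0.45, Aph1a at 0.56, Clic5 at 0.46, Slc38a4 at 0.58 and Ldb3 at 0.55 were higher, and Nos1 at -0.58 and Asb15 at -0.79 lower. The other 3, of 3051 tested probe sets without a single listed gene, were higher in JA16.

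Of the genes of the Y chromosome, Eif2s3y had intensities between 592.5 and 4063 over the 20 samples, Kdm5d between 107.5 and 376.7, and Uty between 11.5 and 288.8, in part under the intensity filter. Xist, expressed from an inactive X chromosome, had an intensity of 434 in JA16 replicate 10, where Eif2s3y was 2330, and between 2.1 and 55.0 in the other samples.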
